A study of Mus musculus with 2 samples.

How the data were processed

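The series profiled spleen T cells of female C57/BL6N mice by single-cell RNA sequencing. Per the labels, 3 groups of 3 mice received saline, or remimazolam at 6 mg/kg with spleens taken 4 h or 8 h later. The labels put the saline group at 0 h, so no saline group was taken at 4 h or 8 h. Remimazolam is a short-acting benzodiazepine, which the series title calls an agonist of the GABA(A) receptor. The cells of the 3 mice of a group were pooled under 1 sample tag, an antibody-borne oligonucleotide that marks all cells of a group. The 3 tagged pools were then captured and sequenced together on the BD Rhapsody platform. The deposited samples are the whole-transcriptome library and the sample-tag library of that single capture. The deposited description gives tag 8 to the saline group (control), tag 10 to the 4 h group and tag 9 to the 8 h group. The labels describe the sort in different ways, as CD45+CD3+CD5+ cells in one place and as CD45+ cells in another, and which of them applied is not settled by the labels.

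Per the file headers, the authors ran the BD Rhapsody WTA Multiplex pipeline, version 1.9.1, on the GRCm38 genome with GENCODE M19. The aligner inside it is not given in the sources used here. The deposited expression table holds integer molecule counts per putative cell and gene, which the authors obtained as unique molecular identifiers adjusted by recursive substitution error correction. That correction removed 9.28% of 54055530 raw molecules. The deposited tag tables hold integer read counts per cell and tag, and the deposited calls name 1 tag, a multiplet or no call for each cell. The deposited matrices of molecules were compared with the expression table, held the same counts and were not used further. The files give genes by symbol only, so coordinates were looked up by symbol in GENCODE M21 on GRCm38.

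The files held 17299 putative cells, 19837 genes, 49040075 molecules and 268220751 reads, or 5.47 reads per molecule. The authors' calls put 16174 cells under a single tag in use. A further 1063 cells (6.14%) were called multiplets, 60 were undetermined and 2 were called for a tag that no group carried. All of these were left out, since their treatment is unknown. Cells were kept with at least 200 genes and under 25% of molecules from mitochondrial genes, which left 16123 cells. Doublets between groups were removed through the authors' multiplet calls. Doublets within a group were scored with Scrublet in scanpy at an expected rate of 3%. Its automatic threshold called 5 of 16123 cells, so it did not work on these data, and no cell was removed by it. The multiplet calls imply that 531.5 kept cells, or 3.30%, hide a doublet within a group. An alternative removed the 457 cells whose scores lay above the score at that rank, which is fewer because tied scores at that rank were kept, and whether these cells were doublets is not known. Ambient RNA was not corrected.

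Counts were scaled to 10000 molecules per cell and log-transformed, and 2000 variable genes, 30 principal components and 15 neighbours were used for Leiden clustering at resolution 1.0 with seed 1. T cell receptor and immunoglobulin segments, haemoglobins, mitochondrial and ribosomal protein genes and Xist did not enter the variable genes. Clusters were named from 21 marker sets, and the authors' own cluster names were not used here. Cell classes below are therefore rebuilt, and a difference from the study may come from the rebuilt names. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9. R 4.3.3 with edgeR 4.0.16 gave the trimmed mean of M-values (TMM) factors.

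Each treatment is represented by 1 sample tag, so there is no replicate check of any value, and no test, p-value or count of differing genes between treatments is given. Differences between the mice of a group cannot be seen in pooled cells. Shares of cells have exact Clopper-Pearson 95% intervals. For genes, molecules were summed over the cells of a class and tag and divided by the total of that class and tag, which gives counts scaled to a common total in the customary unit, CPM. Ratios of CPM have exact conditional-binomial 95% intervals. In list medians no prior was added, and a member without molecules in 1 treatment was set to 3 molecules there. A prior of 0.5 molecules was used only in the alternative with no minimum of molecules. Intervals and floors cover counting error only. The comparisons were 4 h against control, 8 h against control and 8 h against 4 h. Both comparisons with saline share the control pool, so its own sampling error enters both.

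The depth in molecules was close to equal between pools. The control, 4 h and 8 h pools held 14332312, 14874247 and 14784871 molecules in kept cells, and 13979891, 14318140 and 14286808 in T cells. In all T cells a count of 3 molecules corresponds to 0.215, 0.210 and 0.210 CPM. In the regulatory T-like class, with 706986, 759969 and 853937 molecules, it corresponds to 4.24, 3.95 and 3.51 CPM. Tag reads were fewer in the control pool, with a median of 217 per called cell against 487 at 4 h and 440 at 8 h. The called tag held a median of 98.8%, 99.2% and 99.3% of them.

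The genes named in the text follow a fixed rule. For each time against control in all T cells, it takes the 10 genes ranked highest and the 10 ranked lowest by the bound of the 95% interval nearest to 1. In regulatory T, conventional CD4 and CD8 T cells it takes the top 5 each way. Only genes with at least 20 CPM in either treatment entered. Immunoglobulin and T cell receptor segments, haemoglobins, mitochondrial and ribosomal protein genes, Xist, predicted genes without a family name and marker genes of contaminating cells were left out. The rule also names the members with most molecules of each fixed list, and 8 genes whatever their value: Foxp3, Il2ra, Ctla4, Ikzf2, Cd69, Il2, Ifng and Tspo. Any other gene is said to have been chosen after its values were seen. Some genes that the rule names are not reported here.

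A set of 19 gene lists was fixed. They cover early activation, late activation and costimulation, T cell receptor signalling, cytokines and effector molecules, inhibitory receptors, the regulatory T cell phenotype, naive and homing genes, the glucocorticoid response, the interferon response, and heat shock and dissociation. The others are NF-kB targets, proliferation, apoptosis and p53, glycolysis, oxidative phosphorylation, ribosomal proteins, the circadian clock, benzodiazepine and GABA(A) receptor genes, and calcium handling. Members needed at least 10 molecules in both treatments together. Each list is given as its median log2 ratio, with a 95% interval from 1000 Poisson draws of the counts. It also has a percentile among 10000 random lists of the same size, drawn within 100 expression ranks of each member, which describes these libraries and is not a test. Members at least 1.25 times higher or lower were counted.

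The share of T cells with a Foxp3 molecule was computed after each cell was thinned to 1000 molecules, with shallower cells left out. The ratios, their intervals, the gene ranking and the list percentiles were run on simulated data in which 200 genes were given known folds. Counts were Poisson draws per gene and pool, so coverage near 95% was built in. Clustering, naming, shares, thinning and differences between cells or mice were not simulated. The 95% intervals covered the true ratio for 95.0% of 6497 genes at 4 h and 95.4% of 6488 at 8 h. All 20 genes the rule named in each comparison had a simulated difference.

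The cell filter, clustering settings, marker sets, gene lists, named-gene rule, comparisons and most alternatives were chosen before the data were examined. The thresholds for naming a cluster, the doublet rule, the list medians singled out as main answers, 3 further gene lists (sterol synthesis, PPAR targets and LXR targets), most tests of explanations and 3 added alternatives were decided after. The alternatives fixed beforehand were no cell filter, a stricter filter (at least 500 genes and under 10% mitochondrial molecules), removal of doublets called from expression (run with the later rule above) and a tag holding at least 90% of a cell's tag reads. Further ones were clustering at resolutions 0.5 and 2.0, gating on molecules in place of clusters, and the Foxp3 share without thinning or thinned to 500 molecules. Gene values were also recomputed with TMM factors, with each cell weighted equally, with totals that leave out ribosomal, mitochondrial, immunoglobulin and haemoglobin genes, and from reads in place of molecules. List members were taken with no minimum or at least 50 molecules, and named genes from at least 5 CPM. The last computed all T cell values with each cluster weighted by its overall share, so that the mix of clusters is fixed. Every alternative set of cells was clustered anew, so its classes can hold other cells. The 3 alternatives added later define natural killer T-like cells by a Klrb1c or Zbtb16 molecule, leave the natural killer T-like cluster out, and apply the stricter filter with the first clusters kept.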

Results

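The data describe single spleen T cells of mice 4 h or 8 h after remimazolam, and of mice given saline, in 3 pools of 3 mice each. After filtering, 5267 control, 5433 4 h and 5423 8 h cells remained. The median cell held 2530, 2510 and 2512 molecules and 1284, 1282 and 1282 genes, and the median mitochondrial share was 9.81%, 9.76% and 9.97%. T cells made up 5130, 5245 and 5248 of these, or 97.4%, 96.5% and 96.8%, a share that a CD45+CD3+CD5+ sort would set and a CD45+ sort would not. The study's title asks about T cell activation and the phenotype of regulatory T cells.

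The cells fell into 16 clusters. Conventional CD4 and CD8 T cells were the most frequent. A regulatory T-like cluster was led by Foxp3, Il2ra, Lrrc32, Ikzf2 and Ctla4, and a CD4 memory-like one by Itgb1, Maf, S100a4 and Cxcr3. A CD8 memory-like cluster was led by Ccl5 and Ly6c2, and also by the natural killer receptor genes Klra7, Klre1 and Klra6. It was mixed, since 64.6% of its cells had a Cd8a molecule and 17.7% one of the γδ receptor gene Trdc, and at resolution 2.0 it parted into 593 CD8 memory-like cells and 438 unnamed cells led by Ccl5, Klra7 and Klre1. A natural killer T-like cluster was led by Klrb1c, Cxcr6, Ccr2 and Zbtb16, the last of which encodes the transcription factor of innate-like T cells. A small γδ-like cluster was led by Tmem176a, Tmem176b, Il17rb and Tcrg-C1, and 21.2% of its 33 cells had a Trdc molecule. Since cells with Trdc also lay in the mixed CD8 memory-like cluster, this small cluster does not measure the share of γδ T cells. A pair of T cell clusters had no name under the marker rule: one led by Egr3, Nr4a1, Nr4a3 and Egr2, and one by Myb, Sox4 and Eomes. An interferon-response cluster, a cycling cluster, B cells, myeloid cells and neutrophils made up the rest.

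As a ratio to control, the natural killer T-like class differed most among the T cell classes, and in percentage points at 4 h conventional CD4 T cells did. It made up 0.858% of T cells in the control pool (95% interval 0.624 to 1.15), 2.40% at 4 h (2.01 to 2.85) and 1.73% at 8 h (1.40 to 2.12). These shares rest on 44, 126 and 91 cells. The ratio to control was 2.80 (1.97 to 4.04) at 4 h and 2.02 (1.40 to 2.97) at 8 h. When such cells were defined by a Klrb1c or Zbtb16 molecule, a choice made after the data were seen, the ratios were 1.74 and 1.20. Conventional CD4 T cells made up 41.0% (39.6 to 42.3), 36.9% (35.6 to 38.2) and 39.2% (37.9 to 40.6). Their ratio to control was 0.901 (0.847 to 0.959) at 4 h and 0.958 (0.901 to 1.02) at 8 h, and the latter became 1.03 when cells were gated on molecules.

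CD8 T cells made up 30.9%, 31.3% and 29.0% of T cells in the control, 4 h and 8 h pools, with ratios to control of 1.01 (0.946 to 1.09) and 0.937 (0.873 to 1.01). The mixed CD8 memory-like class made up 6.51%, 7.0% and 6.50%, and 3.90%, 3.74% and 3.75% at resolution 2.0. CD4 memory-like cells made up 3.63%, 4.25% and 4.57%, with ratios of 1.17 (0.961 to 1.43) and 1.26 (1.04 to 1.54). Under the stricter cell filter they made up 6.97%, 7.43% and 8.16%, and 31.4% of the cells of that cluster had a Foxp3 molecule. The γδ-like cluster, which does not hold all cells with Trdc, held 13, 12 and 8 cells. Among all kept cells, B cells made up 2.34%, 2.85% and 2.93%, myeloid cells 0.171%, 0.368% and 0.240%, and neutrophils 0.0949%, 0.239% and 0.0553%. Myeloid shares rest on 9, 20 and 13 cells and neutrophil shares on 5, 13 and 3. A CD45+CD3+CD5+ sort would remove B cells, myeloid cells and neutrophils, and a CD45+ sort would keep them. T cells at 97.4%, 96.5% and 96.8% of kept cells argue against a CD45+ sort alone. The shares of the other cells are then what passed a T cell sort, and do not measure the make-up of the spleen. Transcripts of the plasma cell marker list summed to 61.7, 183 and 85.9 CPM in all kept cells. Those of the neutrophil list summed to 121, 89.6 and 25.9 CPM, unlike the cell shares lower at 4 h than in control. Within T cells the natural killer cell marker list summed to 166, 198 and 183 CPM.

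**Figure D1:**
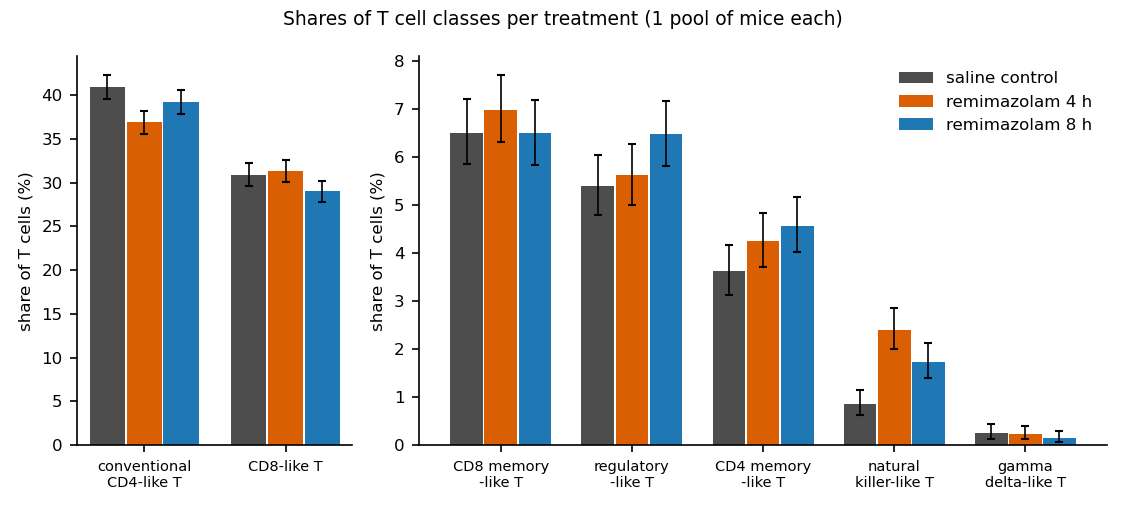
Bars give the share of T cells, in percent, of 7 rebuilt cell classes in the control, 4 h and 8 h pools, and error bars give the 95% Clopper-Pearson interval, which covers counting error only. The natural killer T-like class stood at 0.858%, 2.40% and 1.73%, and the regulatory T-like class at 5.40%, 5.62% and 6.48%.

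The first comparison asks how T cells 4 h after remimazolam differed from those of saline-treated mice. Among the lowest-ranked genes were Tsc22d3, which encodes the glucocorticoid-induced leucine zipper protein GILZ, Ddit4, which encodes a stress-induced inhibitor of mTORC1, and Zfp36l2, whose product promotes decay of messenger RNAs. Higher in the 4 h pool were Bcl3, which encodes an atypical IκB protein, Cpt1a, whose enzyme admits long-chain fatty acids to mitochondria, and the chemokine receptor genes Ccr2 and Cxcr6. Of the fixed gene lists, glucocorticoid response and early activation genes had medians below control and interferon response genes one above it, though most members of each differed by less than the fold that was counted.

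Tsc22d3 stood at 99.8 CPM in the 4 h pool against 148 in control, a ratio of 0.673 (0.629 to 0.721). Ddit4 stood at 157 against 217 CPM, a ratio of 0.725 (0.686 to 0.766), and Zfp36l2 at 763 against 943 CPM, a ratio of 0.809 (0.788 to 0.829). Cxcr4, the receptor for the homing chemokine CXCL12, had a ratio of 0.766 (0.697 to 0.841). The sterol synthesis genes Idi1 and Cyp51 had ratios of 0.692 and 0.722, and Egr3, a transcription factor gene induced through the T cell receptor, one of 0.763 (0.675 to 0.861). The other genes at this end were Dnah8 at 0.718, Pdlim4 at 0.697 and Mtss1 at 0.773. On GRCm38 in GENCODE M21, Tsc22d3 lies on chromosome X from 140539528 to 140600659, Ddit4 on chromosome 10 from 59949669 to 59951834, and Zfp36l2 on chromosome 17 from 84183931 to 84187947, all protein-coding genes on the minus strand.

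At the other end, Bcl3 stood at 40.6 CPM in the 4 h pool against 24.5 in control, a ratio of 1.65 (1.44 to 1.9). Cpt1a stood at 86.0 against 58.5 CPM, a ratio of 1.47 (1.34 to 1.61). Bcl3 lies on chromosome 7 from 19808462 to 19822770 on the minus strand, and Cpt1a on chromosome 19 from 3322334 to 3385733 on the plus strand. Ccr2 had a ratio of 1.70 (1.47 to 1.98) and Cxcr6 one of 1.40 (1.28 to 1.53). Both genes lead the natural killer T-like cluster, and with the mix of clusters held fixed their ratios were 1.29 and 1.12. Il18rap, which encodes a chain of the interleukin-18 receptor, stood at 1.66 (1.40 to 1.97), and P2rx7, which encodes an ATP-gated channel, at 1.49 (1.28 to 1.73). The interferon-induced gene Usp18 stood at 1.5 (1.26 to 1.80), the lysosomal sulfatase gene Arsb at 1.59 and Prrt1 at 1.43. The chemokine gene Xcl1 stood at 1.48 (1.26 to 1.74), with 13.8% of its 4 h molecules from 1 cell. Xcl1 is in the natural killer T marker set, so its ratio can include the larger share of that class.

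**Figure D2:**
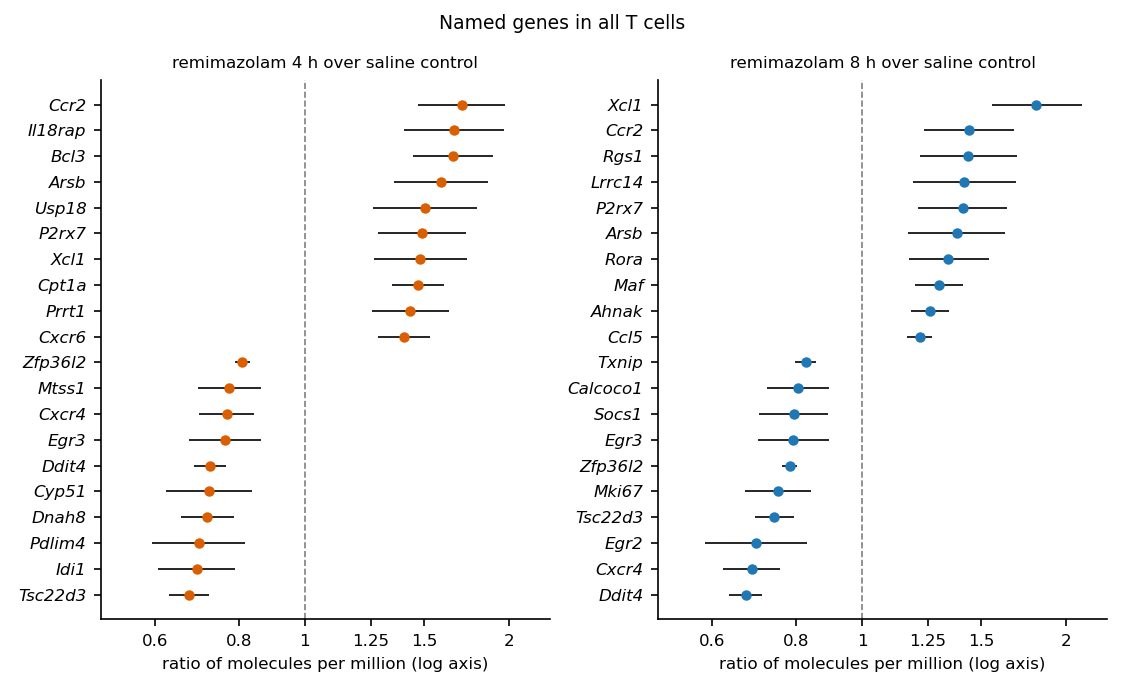
Points give the ratio of CPM in all T cells to the control pool on a log axis, for the 20 genes named at 4 h and the 20 named at 8 h, and lines give the 95% counting interval. At 4 h they run from Tsc22d3 at 0.673 to Ccr2 at 1.70, and at 8 h from Ddit4 at 0.674 to Xcl1 at 1.81.

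The median of early T cell activation genes lay slightly below control at 4 h, with few members past the fold that was counted. The early activation list had a median log2 ratio of −0.07 (−0.12 to −0.02), at percentile 0.010 of the random lists, with 2 of its 20 members counted as higher and 1 as lower. Cd69, the early activation antigen, had a ratio of 0.908 (0.833 to 0.988), Egr1 one of 0.833, Dusp2 0.929, Junb 0.926 and Jund 1.09. Il2 stood at 0.803 (0.582 to 1.1), a difference not detectable at this depth. Ifng, the type II interferon gene, was counted as 55 molecules against 24, a ratio of 2.24 (1.36 to 3.78) that was 1.34 with each cell weighted equally. Late activation and costimulation genes had a median of 0.06 (0.03 to 0.18), with Cd27 at 1.04, Cd28 at 0.95, Icos at 1.02 and Slc3a2 at 1.03. T cell receptor signalling genes had a median of 0.01 and none of its 19 members was counted as higher or lower. Ptprc stood at 1.01, Lck at 1.00, Cd3e at 1.03 and Cd3g at 1.01.

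The glucocorticoid response list had a median log2 ratio of −0.12 (−0.22 to −0.06) at 4 h, below all 10000 random lists, with 5 of 16 members counted as lower and 2 as higher. Its members with most molecules were Btg1 at 0.960, Txnip at 0.838 and Klf13 at 1.05. Interferon response genes had a median of 0.17 (0.11 to 0.23), above all random lists, with 6 of 24 members higher and 0 lower. The abundant members Ifi203 at 1.01, Ifi47 at 1.06 and Ifi27l2a at 1.04 stood near the control level. Rsad2 at 1.59 and Mx1 at 1.42, both chosen after their values were seen, stood above it. NF-kB targets had a median of 0.08 (0.03 to 0.17), with Nfkbia at 1.1, Traf1 at 1.15, Nfkb1 at 1.03 and Cflar at 0.983.

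Glycolysis genes had a median log2 ratio of 0.07 (0.03 to 0.11) at 4 h, at percentile 99.4, and none of the 17 members was counted as higher or lower. Among them, Gapdh stood at 1.04, Aldoa at 1.07, Pkm at 1.06 and Ldha at 1.03. Proliferation genes had a median of 0.10 (0.04 to 0.18) at percentile 99.5, with Tubb5 at 0.967, Pcna at 1.04 and Top2a at 1.04, and this median was −0.07 with the mix of clusters held fixed. Oxidative phosphorylation genes stood at 0.01 and ribosomal protein genes at −0.02, with Uqcrh at 1.02, Rps24 at 0.966 and Rplp1 at 0.956. Heat shock and dissociation genes stood at −0.02, with Hsp90ab1 at 0.985 and Hspa8 at 1.02. Apoptosis and p53 genes stood at 0.00, with Mcl1 at 1.01 and Bcl2 at 0.844. Naive and homing genes stood at −0.03, with Tcf7 at 1.08, Il7r at 0.972 and Lef1 at 0.986. Calcium handling genes stood at 0.01.

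Cytokine, inhibitory receptor and clock genes and the benzodiazepine and GABA(A) receptor list complete the 4 h comparison. Cytokines and effector molecules had a median log2 ratio of 0.02 (−0.07 to 0.19), with Ltb at 1.01, Ccl5 at 1.28, Gzma at 1.19 and Prf1 at 1.05. Inhibitory receptor genes had a median of 0.10 (0.02 to 0.27), with Cd5 at 0.994, Btla at 0.935, Tox at 1.07 and Nt5e at 1.14. Circadian clock genes had a median of 0.12 (0.01 to 0.31), at percentile 89.6 of the random lists, with 7 of 17 members counted as higher and 0 as lower. Rora, which is also in the CD4 memory marker set, stood at 1.34, Dbp at 1.09, Cry1 at 1.05 and Nr1d2 at 0.971. Only 4 of the 21 genes of the benzodiazepine and GABA(A) receptor list reached 10 molecules, and their median was 0.00. Most of these 4 do not encode a GABA(A) receptor subunit, so the median does not describe that receptor. Tspo, which encodes the peripheral benzodiazepine-binding translocator protein, stood at 104 against 100.0 CPM, a ratio of 1.04 (0.965 to 1.12). Gabarap stood at 1.02 and Gabbr1, a GABA(B) receptor gene, at 0.981. Gabrr2, the only GABA(A)-type subunit gene with at least 10 molecules, stood at 0.724 (0.593 to 0.883). No molecule of Gabra5, Gabra6, Gabrb2 or Gabrr1 was detected.

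The next comparison asks how T cells 8 h after the drug differed from saline. Ddit4, Cxcr4, Tsc22d3 and Zfp36l2 were the 4 lowest-ranked genes. The activation-induced transcription factor gene Egr2 was also lower in the 8 h pool, as were molecules of the proliferation gene Mki67, though not the number of cells with one. Higher were the chemokine genes Xcl1 and Ccl5, Ccr2, the transcription factor genes Maf and Rora, and Rgs1, which encodes a regulator of chemokine receptor signalling. The median of late activation and costimulation genes lay above control and that of glucocorticoid response genes below it, with most members of each short of the fold that was counted. The median of interferon response genes lay nearer to control.

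Ddit4 had a ratio of 0.674 (0.637 to 0.712) at 8 h, Cxcr4 of 0.688 (0.624 to 0.758), Tsc22d3 of 0.742 (0.694 to 0.793) and Zfp36l2 of 0.782 (0.762 to 0.802). Cxcr4 lies on chromosome 1 from 128588199 to 128592293 on the minus strand. Egr2 stood at 0.698 (0.587 to 0.828), Mki67 at 0.752 (0.672 to 0.841) and Socs1, a cytokine signalling inhibitor gene, at 0.793. Egr3 stood at 0.791 (0.702 to 0.892), but at 0.994 under the stricter cell filter, where Mki67 stood at 0.872. An Mki67 molecule was found in 81 control and 91 8 h cells, and the cycling cluster made up 0.819% and 1.01% of T cells, a ratio of 1.23 (0.807 to 1.9). Txnip stood at 0.825 (0.795 to 0.857) and Calcoco1 at 0.805. Xcl1 stood at 34.0 against 18.8 CPM, a ratio of 1.81 (1.55 to 2.11). Its molecules lay in 160 8 h cells and 124 control cells, with 13.6% of the 8 h molecules from 1 cell. Ccr2 had a ratio of 1.44 (1.24 to 1.68), which was 1.05 without the natural killer T-like cluster that it leads. Maf stood at 93.7 against 72.1 CPM, a ratio of 1.30 (1.20 to 1.41) that was 1.09 with the mix of clusters held fixed. Ccl5 stood at 337 against 277 CPM, a ratio of 1.22 (1.17 to 1.27), Rora at 1.34, Rgs1 at 1.44, P2rx7 at 1.41 and Ahnak at 1.26. Xcl1 is in the natural killer T marker set, and Rora and Ahnak are in the CD4 memory one. Both classes had a larger share at 8 h, so these ratios can include the mix of clusters. Their values with the mix held fixed are not given here. Lrrc14 stood at 1.41 and Arsb at 1.38.

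The early activation list had a median log2 ratio of 0.02 (−0.05 to 0.07) at 8 h, with 4 of 20 members counted as higher and 2 as lower. Under the stricter cell filter it was 0.08. Cd69 stood at 1.06 (0.973 to 1.15), Jund at 1.15, Junb at 1.03, Egr1 at 0.929 and Dusp2 at 0.889. Il2 stood at 0.826, and Ifng at 2.0 (1.20 to 3.4) from 49 molecules against 24. Late activation and costimulation genes had a median of 0.19 (0.07 to 0.23), above all 10000 random lists, and one of 0.10 with the mix of clusters held fixed. Only 1 of its 13 members was counted as higher, and Slc3a2 stood at 1.09, Cd27 at 1.04, Icos at 1.01 and Cd28 at 0.992. T cell receptor signalling genes had a median of 0.01. Cytokines and effector molecules had a median of 0.12 (0.02 to 0.27), with 7 members higher and 1 lower. That median was 0.28 with each cell weighted equally and 0.0032 with the mix of clusters held fixed. Inhibitory receptor genes had a median of 0.12 (0.04 to 0.23), which was −0.01 with the mix held fixed.

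The glucocorticoid response list had a median log2 ratio of −0.09 (−0.18 to −0.03) at 8 h, below all 10000 random lists, with 4 members counted as lower and 1 as higher. Interferon response genes had a median of 0.06 (0.02 to 0.12) and NF-kB targets one of 0.05 (0.02 to 0.13). Circadian clock genes had a median of 0.16 (−0.01 to 0.33), at percentile 99.3, with 6 of 17 members counted as higher and 0 as lower. Dbp stood at 1.18, Cry1 at 0.951 and Nr1d2 at 1.00. Proliferation genes stood at 0.04 (−0.00 to 0.11), at 0.12 under the stricter filter and at −0.03 with the mix of clusters held fixed. Glycolysis genes stood at 0.03, oxidative phosphorylation at 0.01, ribosomal proteins at −0.02 and heat shock and dissociation genes at 0.01. Apoptosis and p53 genes had a median of −0.05 (−0.09 to −0.01). Naive and homing genes stood at −0.01 and calcium handling genes at 0.01. The same 4 members of the benzodiazepine and GABA(A) receptor list had a median of −0.06. Tspo stood at 1.00 (0.931 to 1.08) and Gabrr2 at 0.828 (0.683 to 1.00).

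**Figure D3:**
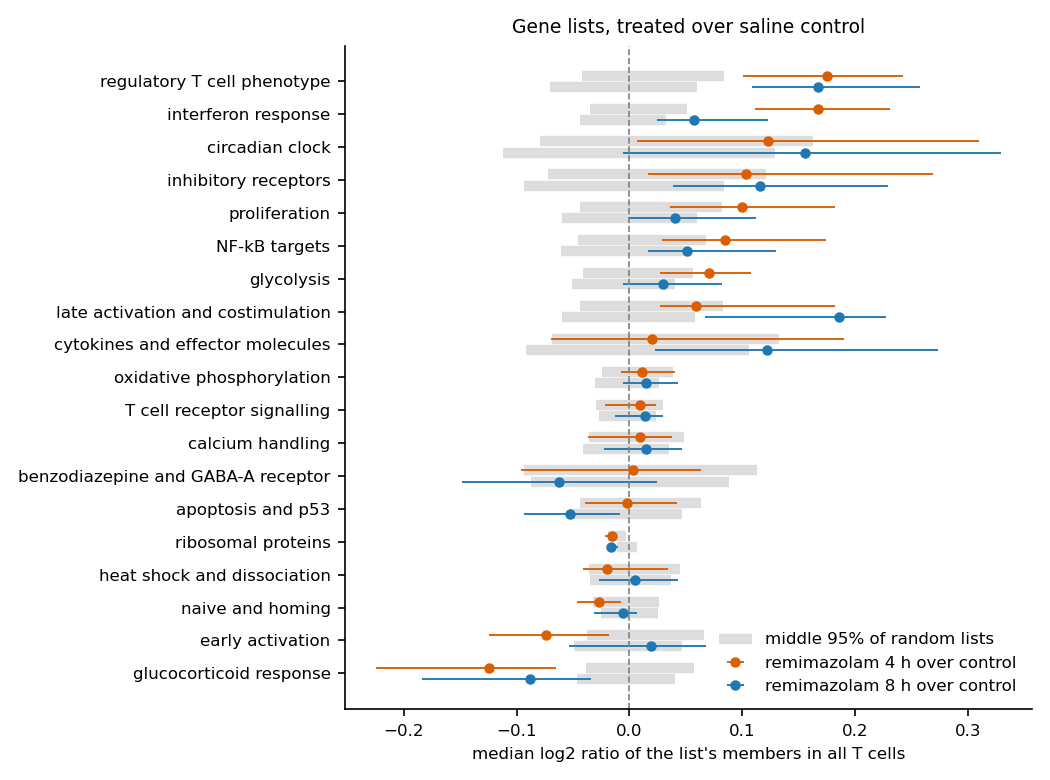
Points give the median log2 ratio to the control pool of 19 gene lists in all T cells at 4 h and at 8 h, lines give its 95% counting interval, and grey bars give the middle 95% of random lists matched for expression. The glucocorticoid response list lies at −0.12 and −0.09, and the interferon response list at 0.17 and 0.06.

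The pools at 8 h and 4 h were also set against each other, which leaves the control pool out. The sterol synthesis genes Idi1 and Cyp51 differed between them, as did Cpt1a, Mki67 and the interferon response list. Idi1 was 1.46 times higher at 8 h (1.28 to 1.67) and Cyp51 1.42 times higher (1.23 to 1.64), while Cpt1a had a ratio of 0.786 (0.722 to 0.856). Dnah8, a dynein chain gene, stood at 1.33 (1.22 to 1.46), Mki67 at 0.677 (0.607 to 0.755) and Bcl3 at 0.80 (0.707 to 0.906). The interferon response list had a median log2 ratio of −0.12 (−0.15 to −0.06), below all random lists, and early activation genes had one of 0.06. Zfp36l2 at 0.967 and Ddit4 at 0.929 differed little between the times. The ratio of natural killer T-like shares was 0.722 (0.545 to 0.953).

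In regulatory T-like cells, the question is whether their number or phenotype differed after the drug. Their share of T cells was near that of the control pool at 4 h and higher at 8 h. Foxp3, which encodes the factor that specifies the lineage, was near control at 4 h within the class. At 8 h its molecules were lower there, though not with a stricter cell filter and new clusters. The share of cells in the class with a Foxp3 molecule was near control at 8 h. The median of the glucocorticoid response list lay below control at both times within the class. With a stricter cell filter and new clusters it lay below control at neither time, and with the first clusters kept only at 8 h. Cd69 was lower at 4 h. Foxp3, Il2ra, Ctla4 and Ikzf2 help to define this class, so their levels inside it are limited by how the class was made.

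The class held 277 control, 295 4 h and 340 8 h cells, or 5.40% (4.80 to 6.05), 5.62% (5.02 to 6.28) and 6.48% (5.83 to 7.18) of T cells. The ratio to control was 1.04 (0.881 to 1.23) at 4 h and 1.20 (1.02 to 1.41) at 8 h. At resolution 0.5 the class was wider, with 9.06%, 9.84% and 10.9% of T cells and ratios of 1.09 and 1.21. Independently of clusters, 3.41% of control T cells thinned to 1000 molecules had a Foxp3 molecule (2.93 to 3.94), against 3.34% at 4 h (2.86 to 3.86) and 3.64% at 8 h (3.15 to 4.19). A difference in this share was not detectable at this depth. The background, read in CD8-like cells thinned in the same way, was 0.316%, 0.122% and 0.264%. Median depth before thinning was 2538, 2521 and 2524 molecules in T cells and 2660, 2640 and 2653 in CD8-like cells. In all T cells, Foxp3 had a ratio to control of 1.02 (0.923 to 1.12) at 4 h and 1.02 (0.930 to 1.13) at 8 h, and with the mix of clusters held fixed it stood at 0.962 and 0.879. It lies on chromosome X from 7573644 to 7595245 on the plus strand.

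Over all T cells, the regulatory T cell phenotype list had a median log2 ratio of 0.17 at both times, with intervals of 0.10 to 0.24 at 4 h and 0.11 to 0.26 at 8 h. With the mix of clusters held fixed it was 0.10 and 0.03. Il2ra, the high-affinity interleukin-2 receptor chain, stood at 1.16 (1.05 to 1.29) and 1.19 (1.07 to 1.32), but at 1.07 and 1.02 with the mix held fixed, and at 1.04 at 4 h with each cell weighted equally. The inhibitory receptor gene Ctla4 stood at 1.17 and 1.12, and at 1.09 and 0.970 with the mix held fixed, and Izumo1r, the folate receptor 4 gene, at 1.07 and 1.1. Ikzf2 stood at 1.07 and 1.08, and at 0.993 and 0.957 with the mix held fixed. Within regulatory T-like cells the list median was 0.11 (0.01 to 0.21) at 4 h and 0.05 (−0.05 to 0.18) at 8 h. The stricter cell filter put these at 0.22 and −0.07, and at 0.05 and 0.02 with the first clusters kept.

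Within regulatory T-like cells, Foxp3 had a ratio of 0.974 (0.879 to 1.08) at 4 h and 0.877 (0.791 to 0.972) at 8 h. The 8 h ratio was 1.03 under the stricter cell filter, whose clusters were made anew, and 0.941 with the first clusters kept. A Foxp3 molecule was found in 69.7% of control, 72.2% of 4 h and 69.7% of 8 h cells of the class. Thinned to 1000 molecules, these shares were 53.1%, 52.9% and 50.7%. Ratios at 4 h and 8 h were 1.02 and 0.984 for Il2ra, 1.11 and 1.00 for Ctla4, and 0.954 and 0.929 for Ikzf2. Cd69 stood at 0.700 (0.506 to 0.965) and 0.739 (0.543 to 1.00). Tsc22d3 stood at 0.685 and 0.678. The glucocorticoid response list had a median log2 ratio of −0.26 (−0.39 to −0.05) and −0.25 (−0.38 to −0.07), but stood at 0.13 and 0.05 under the stricter filter, and at 0.06 and −0.05 under it with the first clusters kept. The interferon response list had a median of 0.14 (0.01 to 0.29) at 4 h. Early activation genes stood at −0.18 (−0.32 to 0.05) at 4 h and 0.11 at 8 h, and the former was 0.37 under the stricter filter and 0.03 with the first clusters kept.

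The genes named by rank in this small class rest on few molecules. Lower at 4 h were Nrn1, which encodes neuritin, at 0.341 (0.240 to 0.478), and Irf8 at 0.275, Ddit3 at 0.164, Btf3l4 at 0.26 and Abcg3 at 0.254. Under the stricter filter with new clusters Nrn1 stood at 3.06, Irf8 at 0.589 and Ddit3 at 0.629, but there Nrn1 was a leading gene of the CD4 memory-like cluster, so the class held other cells. With the first clusters kept, the same filter put them at 0.426, 0.259 and 0.158. Higher at 4 h were Tesc at 2.68 (1.52 to 4.97), Cerk at 3.31 and Tmem161a at 3.88. The cytokine gene Lif, at 4.39 (1.91 to 11.7), and the Ly6 family gene Ly6c2, at 4.42, had 48.5% and 68.4% of their 4 h molecules in 1 cell, and at 8 h Lif had 1 molecule against 7 in control. At 8 h Ly6c2 stood at 7.04 and Nr4a2 at 7.87, with 67.6% and 63.2% from 1 cell, and the stricter filter put Ly6c2 at 0.735, or 0.659 with the first clusters kept. Gbp2b at 6.35, Timeless at 5.17 and Dnajb13 at 5.80 were also higher at 8 h. Lower at 8 h were Cdca8, with 1 molecule against 15, and Angptl2 at 0.174, Dhrs3 at 0.155, Pms1 at 0.218 and Dtnbp1 at 0.252. At resolution 0.5 Timeless stood at 1.59, Angptl2 at 0.727 and Pms1 at 0.640.

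In conventional CD4 T cells, the same comparisons ask about the helper lineage. Bcl3 and Cpt1a were among the genes higher at 4 h, and Cxcr4 and Ddit4 were lower at both times. At 4 h, Neb, which encodes the muscle protein nebulin, stood at 3.95 (2.65 to 6.04) and at 8 h at 0.480 (0.241 to 0.912). Also higher at 4 h were the fatty acid elongase gene Elovl6 at 1.84, Bcl3 at 1.67, Cpt1a at 1.55 and the kinase gene Pim2 at 1.5. Lower at 4 h were Fam207a at 0.510, Cxcr4 at 0.630, Tsc22d3 at 0.660 and Ddit4 at 0.711. At 8 h, Cxcr4 stood at 0.560, Hist2h2be at 0.552, Ddit4 at 0.648, Tsc22d3 at 0.733 and Zfp36l2 at 0.752. Tmem80, Srp54a and Rhobtb2 each stood at 1.54, Myo6 at 1.51 and Itgb3bp at 1.64. Early activation genes had a median log2 ratio of −0.07 (−0.19 to 0.01) at 4 h and 0.11 (−0.01 to 0.20) at 8 h, and the stricter filter put the latter at −0.01. Glucocorticoid response genes had medians of −0.08 (−0.24 to 0.00) and −0.08 (−0.19 to 0.03), and the stricter filter put the latter at −0.20. Naive and homing genes stood at 0.05 at 8 h, which the stricter filter put at −0.0023.

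In CD8 T cells, Bcl3 and the cholesterol exporter gene Abca1 were higher at 4 h, and Cxcr4 was lower at 8 h. Bcl3 stood at 2.09 (1.59 to 2.78), Abca1 at 1.92 (1.53 to 2.42), Ap1s3 at 1.96, Qtrt2 at 1.85 and Pim2 at 1.35. Insig1, which encodes a sterol-sensing regulator of SREBP processing, stood at 0.616, Tspan32 at 0.626, Dnah8 at 0.671, Tsc22d3 at 0.691 and Ddit4 at 0.699. At 8 h, Cxcr4 stood at 0.584 (0.494 to 0.689), Zfp729b at 0.557, Eps8l1 at 0.571, Ddit4 at 0.652 and Zfp36l2 at 0.755. Qtrt2 stood at 1.64, Cdk5rap1 at 1.55, Ring1 at 1.47, Trim44 at 1.45 and Zbtb20 at 1.35. NF-kB targets had a median log2 ratio of 0.19 (0.07 to 0.32) at 4 h, with 5 members counted as higher and 0 as lower, and 0.01 at 8 h. The stricter filter put the 4 h median at 0.051. Early activation genes stood at −0.16 (−0.24 to −0.02) and 0.03 (−0.11 to 0.15). Glucocorticoid response genes stood at −0.18 (−0.27 to −0.07) and −0.16 (−0.23 to −0.05), with 5 of 15 members counted as lower at each time. Interferon response genes stood at 0.10 (0.05 to 0.20) at 4 h and 0.01 at 8 h.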

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

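Of the tests in this part, those on the place of tag reads in cells, the coincidence of cell labels, the glucocorticoid response genes, the border of the natural killer T-like cluster and its doublets were chosen only after the result was seen. A signal appeared in sample tags that no treatment carries and that lie outside the comparisons, where tag 11 had 3578754 reads (23.6% of all tag reads) and tag 12 had 2199367 (14.5%), against at most 827 reads for any other unused tag. Cells of another sample inside this capture are argued against, since at most 2.34% of the reads of either tag lay in putative cells, against 80.1% to 82.2% for the tags in use. Free tag spread evenly over the cells is argued against, since 85.3% of the reads inside cells lay in cells with at least 50 reads, while the median cell had 0. A candidate explanation is reads of another library whose cell labels coincide with those of this capture by chance. The putative cells take 1.96% of labels up to the highest one, 884701, and the share of tag 12 reads in them was 1.20 times that, with 1.12 for tag 11, but no biological explanation was tested.

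The median of glucocorticoid response genes lay below control in all T cells of both remimazolam pools, which share 1 control pool, with 5 of 16 members counted as lower and 2 as higher at 4 h, and 4 as lower and 1 as higher at 8 h. A change in the mix of clusters is argued against as the whole source, since with the mix held fixed the list median was −0.16 at 4 h and −0.14 at 8 h on the log2 scale. Lower cell quality in all T cells is argued against, since in stricter cells the medians were −0.12 and −0.05 and the upper bound at 8 h was −0.032, although in regulatory T-like cells the stricter filter gave 0.06 and −0.05 with the first clusters kept. A difference in time of day between the pools, which may move circulating glucocorticoid, stays open. Circadian clock genes, which share Per1 with this list, had medians of 0.12 at 4 h and 0.16 at 8 h in all T cells. These lay at percentiles 89.6 and 99.3 of random lists, with 7 and 6 of 17 members counted as higher and 0 as lower. The 8 h median was 0.0012 with members of at least 50 molecules. In conventional CD4 T cells the clock medians at 4 h and 8 h were 0.03 and 0.03, and in CD8 T cells 0.13 and 0.0001. In regulatory T-like cells they were −0.24 and 0.05, and every interval within these classes holds 0. The drug itself also stays open and untested, as does an unusual control pool. No saline pool was taken at 4 h or 8 h and each group has 1 pool, so drug, time and handling cannot be separated.

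The natural killer T-like class took a larger share of T cells in both remimazolam pools. A shifted cluster border is argued against as the whole source at 4 h, where the ratio of cells with a Klrb1c or Zbtb16 molecule was 1.74 (1.32 to 2.31), but stays open at 8 h, where it was 1.20 (0.890 to 1.62). That gate took 63.2% of the cluster's cells, 0.168% of CD8-like and 0.229% of B-like cells. It is not specific to the cluster, since only 49.5% of the gated T cells lay in it. Klrb1c was also found in 9.79% of the mixed CD8 memory-like cells. Outside the cluster the ratios of gated cells were 1.08 and 0.898. Doublets are argued against as the source of the extra cells, since at most 15.1% of the cluster's cells (the upper bound at 4 h) were as deep as the median tag multiplet, at 4473 molecules, where 32.1% at 4 h and 25.3% at 8 h would be needed. Chance between pooled mice or sorts, those of the shared control pool included, may account for the difference and stays open beside an effect of the drug, because the number of sample tags per treatment was 1.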

How the results depend on the processing

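The gate on Klrb1c or Zbtb16, the removal of the natural killer T-like cluster and the stricter filter with the first clusters kept were chosen after seeing the data. Over 326 results and 3858 alternative values, 3632 lay inside the counting interval of the reported value, 212 moved outside it and 14 reversed. Of the 30 results that answer a comparison, 20 had every alternative inside their interval. Among the named genes, 51 ratios moved and 8 reversed, and among list medians 74 moved and 6 reversed. The stricter cell filter with new clusters, which kept 8406 T cells, put the ratio of Foxp3 in regulatory T-like cells at 8 h at 1.03 (reported 0.877), of Ly6c2 there at 0.707 and 0.735 (4.42 and 7.04) and of Nrn1 at 4 h at 3.06 (0.341). It put log2 medians in that class at 0.13 and 0.045 for glucocorticoid response genes (−0.26 and −0.25) and at 0.22 and −0.074 for the regulatory T cell phenotype (0.11 and 0.05). In all T cells it put early activation at 8 h at 0.080 (0.02), and in conventional CD4 cells early activation at −0.011 (0.11) and naive and homing genes at −0.0023 (0.05). It also put Egr3 in all T cells at 8 h at 0.994 (0.791) and NF-kB targets in CD8 cells at 4 h at 0.051 (0.19). Of 225 class share values 70 moved, among them the CD8 memory-like, CD4 memory-like and regulatory T-like shares given above. With the first clusters kept, the stricter filter put Ly6c2 in regulatory T-like cells at 0.872 and 0.659, glucocorticoid response genes there at 0.062 and −0.053, and early activation in all T cells at 8 h at 0.082. Nrn1 and Foxp3 did not reverse then, at 0.426 and 0.941, so their reversal needed the new clusters. Gating on molecules put the share ratio of conventional CD4 cells at 8 h at 1.03 (0.958), and the Klrb1c or Zbtb16 gate put that of natural killer T-like cells at 1.74 and 1.20 (2.80 and 2.02). Weighting each cell equally put cytokines at 8 h at 0.28 (0.12), and reads put the regulatory T cell phenotype in regulatory T-like cells at 8 h at −0.070 (0.05). With the mix of clusters held fixed, Ikzf2 stood at 0.993 and 0.957 (1.07 and 1.08), proliferation at 4 h at −0.070 (0.10), and at 8 h cytokines at 0.0032 (0.12) and inhibitory receptors at −0.014 (0.12). For these last the reported values include the mix of clusters; otherwise the cause was not tested. From 5 CPM up, 6 of 20 genes in all T cells at 4 h and 5 of 20 at 8 h were named again, because more genes entered. A total of 17 gene ratios had no value under an alternative. The 3 lists written later were not recomputed. No paired analysis was possible because each treatment has 1 sample tag, and for the same reason leave-one-out, DESeq2 and a replicate block were not run. Depth limits regulatory T-like cells most, where 3 molecules are 3.51 to 4.24 CPM.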

Other observations

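Some of the genes named at 4 h act in cholesterol or fatty acid handling. Whether such genes were more frequent there than among all genes was not tested. A set of 3 hypotheses about them was tested. The lists for them were written after the named genes were seen, and all 3 tests were chosen only after those genes. The genes already seen were left out of the lists. In all T cells at 4 h those were the sterol synthesis genes Idi1 at 0.692, Cyp51 at 0.722 and Msmo1 at 0.766, and Insig1 at 0.756, among others.

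Sterol synthesis may have been lower as a group at 4 h. Among 16 other sterol synthesis genes the median log2 ratio was −0.077 (−0.19 to −0.01) in all T cells, at percentile 1.71 of matched random lists. Of these, 11 lay below 1 and 3 were counted as lower. Among those 3 were Sqle, the squalene epoxidase gene, at 0.581 and Mvk, the mevalonate kinase gene, at 0.603, both chosen after their values were seen. The median was 0.02 at 8 h, and 0.13 for 8 h against 4 h, at percentile 99.97. The 4 h median was −0.15 (−0.30 to 0.04) in CD8 T cells, −0.01 (−0.19 to 0.13) in conventional CD4 T cells and 0.33 (−0.52 to 0.44) in regulatory T-like cells. Each of these intervals holds 0, and a difference between classes was not tested. At resolution 2.0, Idi1 and Cyp51 were among the leading genes of a conventional CD4 cluster with 421 control, 340 4 h and 356 8 h cells. The sterol list was not recomputed with the mix of clusters held fixed, so a change in that mix stays open as a source.

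Cpt1a and Abca1 are targets of the lipid-sensing nuclear receptors PPAR and LXR, and activity of these receptors was a candidate explanation for their higher levels at 4 h. The other PPAR targets, 13 with enough molecules, had a median log2 ratio of 0.0077 (−0.06 to 0.07) at 4 h, at percentile 39.3, against 0.56 for Cpt1a itself. The other LXR targets, 11 in number, had a median of 0.047 (−0.04 to 0.12), at percentile 77.7, against a ratio of 1.44 for Abca1 itself. In conventional CD4 T cells the LXR targets had a 4 h median of 0.16 (−0.02 to 0.25), at percentile 99.8. In all T cells both results argue against a shift of the whole group of targets by as much as these genes, and a smaller one stays open.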
